A study of Mus musculus with 30 samples.

How the data were processed

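Bulk RNA sequencing was measured in 30 libraries of mouse prefrontal cortex at postnatal day 40. Per the labels, all mice were of strain C57BL/6J and all libraries belonged to the same batch. Libraries were made with a stranded kit that selects polyadenylated RNA, per the labels' protocols. Genotype is given as heterozygous (HT) or wild type (WT) for a Pten knock-in, treatment as fluoxetine, lithium or vehicle, and sex as female or male. The mutation that was knocked in, the doses, the route, the length of treatment and the time of day at collection are not given in the sources used here. WT mice received only vehicle, so an effect of either drug in WT mice could not be tested.

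Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used with genome build GRCm38. What each tool did, the transcript annotation and any filter on genes are not given in the sources used here. The deposited table holds 18240 genes by 30 libraries, and its values are a signal that the authors made from gene counts divided by 1 size factor per library. In 29 libraries every value was tested to be a whole multiple of the library's smallest step, within 1e-06, and the multiple was taken as the read count. The remaining library, replicate 4 of the lithium-treated HT males, behaved alike, but its step lies too near 1 for the general test of steps. Of the 18240 Ensembl identifiers, 18227 had a symbol and GRCm38 coordinates in the GENCODE annotation, and 13 did not. Recovered totals ran from 24693804 to 33817535 reads per library. Mitochondrially encoded genes took between 4.19% and 6.77% of each library.

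The choices in the rest of this paragraph were made before the data were examined. Genes with a mean of at least 10 normalised reads over all libraries were tested, which left 16780 and set aside 1460. Values were taken to log2 after adding 1 and fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 8 groups, a mean-variance trend and robust estimation. Adjusted p-values are Benjamini-Hochberg values, and genes under 0.05 were called. The main comparisons averaged the sexes with equal weight: genotype (vehicle HT minus vehicle WT), fluoxetine and lithium (each minus vehicle, in HT). Each was also taken within each sex and as male minus female. Further comparisons were fluoxetine HT minus lithium HT, each drug-treated HT group minus vehicle WT, and male minus female over vehicle mice. Gene lists, 58 in all, covered brain cell types, neighbouring tissues, activity-response genes, signalling, metabolism, synapse, stress, hormone response, clock and sex. They were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with adjustment over the 58 lists within a comparison. Counts of called members are given over all genes and adjusted over the list alone.

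A list's score in a library is the mean of its members' log2 values after each gene was centred on its mean over all libraries. Scores of the olfactory bulb and neuroblast list, the striatum list and the blood list were compared with exact 2-sided permutation tests, adjusted over the 6 comparisons within a list. These tests of scores were not among the choices fixed beforehand.

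Genes to be named were fixed by rule. Pten and the sex genes came first. For each main comparison the rule took the 10 higher and 10 lower called genes with the largest change, among those with a symbol other than a clone or predicted-gene name and a mean of at least 50. The other comparisons took 5 in each direction. Where no gene passed, the 5 with the smallest p were taken. For those, the symbol and mean limits were applied as well, a reading of the rule chosen after an unnamed identifier was seen among the unlimited picks. List members with the smallest p were taken as examples. Other genes named in the text were chosen after their values were seen.

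The fits were tested on simulated data for the genotype comparison only, with 50 genes changed at each fold size among 16780. limma called 28 of 50 genes at a fold of 1.25, 40 at 1.5, 49 at 2 and all 50 at 3, with 9 false calls among 176. A quasi-likelihood fit in edgeR 4.0.16 on the recovered reads called 28, 41, 49 and 50, with 11 false calls among 179. Camera at the preset correlation called 2 of 2 changed lists and 0 of 20 unchanged lists. The simulated genes varied independently of each other. This check therefore could not show how the preset behaves for lists whose members vary together.

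Alternatives fixed beforehand were limma without trend and robust estimation, a further TMM rescaling, no filter, a filter at a mean of 50, an added value of 5, the replicate number as a block, fits on only the groups compared, each library left out in turn, camera on ranks and an estimated correlation. Count-based alternatives planned for a table of raw counts, namely DESeq2 and a change of size factors, did not apply to this table. Chosen after seeing the data were the edgeR fit, the olfactory score as a covariate, and fits without the 4 libraries of lowest olfactory score or without the library of highest striatum score. So were medians of the ribosomal protein and oxidative phosphorylation lists without the 2 fluoxetine libraries of highest ribosomal score. Correlations of effects across genes were compared with 100 regroupings of residuals, as were overlaps of called genes, and both were recomputed with separate vehicle HT mice for the effects compared, over 36 ways of parting those 8 mice. Figures were drawn with matplotlib 3.10.9. No library was left out of the main fits. All 435 pairs of libraries differed far beyond counting error, with a chi-squared per gene from 3.47 to 58.3, so no library was a copy of another. Nothing in the labels states that each library came from a separate animal or litter, so the p-values measure only the spread between these samples. Transcripts of pseudogenes and of gene families with near-identical members share reads, so their values are uncertain.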

Results

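Prefrontal cortex from mice carrying a Pten knock-in allele, and from their wild-type counterparts, was profiled after fluoxetine, lithium or vehicle. Pten encodes the lipid phosphatase that opposes PI3K signalling, fluoxetine is a serotonin reuptake inhibitor, and lithium is a mood stabiliser that inhibits GSK3 and inositol monophosphatase. Each of the 6 HT groups (3 treatments in each sex) held 4 libraries, and vehicle WT females and males held 3 each. Recovered totals ran from 24693804 to 33817535 reads per library. Xist, which silences an X chromosome, lay between 20630 and 30826 normalised reads in all female libraries and between 0 and 53.1 in all male libraries. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had at most 1.03 normalised reads in females and at least 286 in males. Pten itself (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, GRCm38) showed no called difference by genotype in transcript level. Its group means ran from 5128 (SD 647, n = 4) normalised reads in fluoxetine HT females to 5597 (SD 632, n = 4) in lithium HT males. The log2 fold change of Pten was -0.02 (SE 0.068, adjusted p = 0.915) for genotype, 0.01 (SE 0.063, adjusted p = 1) for fluoxetine and 0.07 (SE 0.063, adjusted p = 0.653) for lithium. The value for genotype became 0.01 without vehicle HT male replicate 2, and also with the olfactory score as a covariate.

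The genotype comparison asked what the HT state changes in the cortex of vehicle-treated mice. Immediate early genes, which neuronal activity and other stimuli induce quickly, were lower in vehicle HT (n = 8) than in vehicle WT (n = 6) mice. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051) encodes an AP-1 transcription factor and fell by 2.11 on the log2 scale (SE 0.15, adjusted p = 2.63e-09). Its means were 2151 (SD 438, n = 3) and 2178 (SD 423, n = 3) normalised reads in WT females and males, against 566 (SD 52.7, n = 4) and 444 (SD 111, n = 4) in HT. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell by 1.79 (SE 0.149, adjusted p = 2.62e-08). Arc (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), a synaptic plasticity gene, fell by 1.44 (SE 0.187, adjusted p = 5.41e-05). Of the 30 list members, 24 fell, 0 rose and 6 did not pass, and 25 fell adjusted over the list alone. The list's median log2 fold change was -0.98, with adjusted p = 0.000422 with an estimated correlation. Members that did not pass included Ier5 at 0.01, Homer1 at -0.09 and Maff at -0.36. In 8 of 8 vehicle HT libraries the list's score lay below that of every vehicle WT library of the same sex, as the plot of immediate early gene scores shows. Further genes among the 10 most reduced within the limits for naming were Atf3, a stress-induced factor, at -2.03 (SE 0.261), Egr2 at -1.84 (SE 0.151) and Nr4a3 at -1.69 (SE 0.146). The others were Btg2 at -1.59 (SE 0.12), Ccn1 at -1.56 (SE 0.116), Fosl2 at -1.46 (SE 0.153) and Nr4a1 at -1.36 (SE 0.117).

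**Figure D1:**
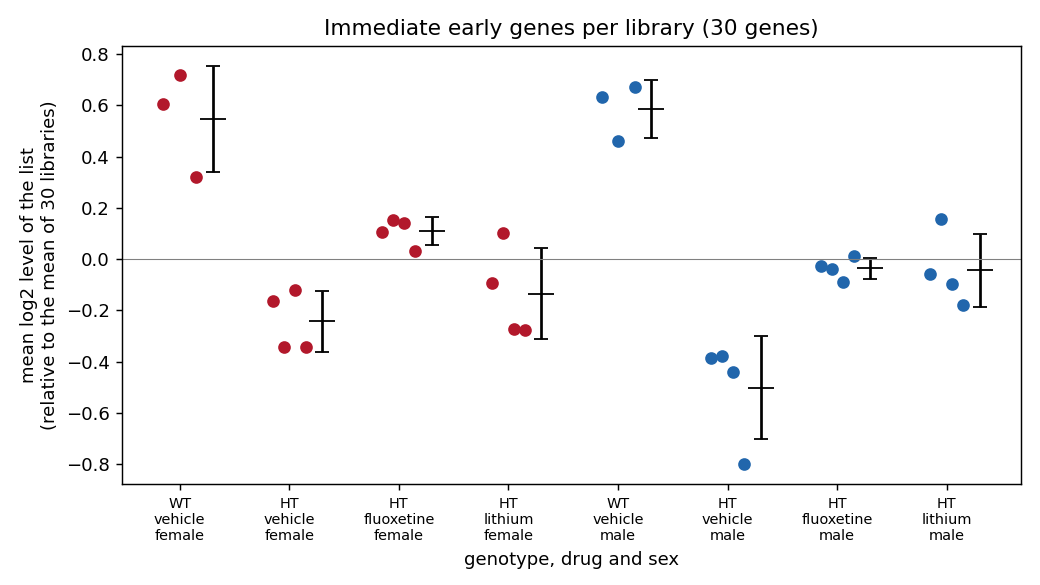
Score of the immediate early gene list (mean centred log2 level of its 30 members) in each library, by group, with the group mean and the standard deviation of its libraries. Vehicle WT libraries lay between 0.32 and 0.72, and vehicle HT libraries between -0.80 and -0.12.

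Microglial transcripts moved the other way. Of 20 microglia markers, 13 were higher in vehicle HT mice and 7 did not pass, with 17 higher adjusted over the list alone. The median was 0.26, with adjusted p = 0.0187 with an estimated correlation. The complement gene C1qa rose by 0.28 (SE 0.043), C1qc by 0.33 (SE 0.057), the integrin Itgam by 0.36 (SE 0.057) and the fractalkine receptor Cx3cr1 by 0.28 (SE 0.051). Some astrocyte markers rose too, but their list did not pass with an estimated correlation. Of 17 astrocyte markers Gjb6, Aldoc and Acsbg1 rose, by 0.22 (SE 0.047), 0.21 (SE 0.055) and 0.17 (SE 0.047), and 7 were higher adjusted over the list alone (median 0.10, adjusted p = 0.169 with an estimated correlation). Their score ran from 0.01 to 0.08 in the 8 vehicle HT libraries and from -0.12 to -0.02 in the 6 WT libraries. Of 22 complement and antigen presentation genes, 3 rose, and these were the C1q genes C1qa, C1qb and C1qc; 3 were higher adjusted over the list alone (adjusted p = 0.0222 at the preset correlation, adjusted p = 0.655 with an estimated correlation). Some extracellular matrix genes were higher as well. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826), a collagen IV chain, rose by 0.44 (SE 0.05, adjusted p = 1.29e-06), Col4a2 by 0.45 (SE 0.054), Lamb1 by 0.24 (SE 0.04) and Lamc1 by 0.27 (SE 0.047). They were 4 of the 6 extracellular matrix and perineuronal net genes of 27 that rose, against 8 higher and 1 lower adjusted over the list alone (adjusted p = 1.21e-06 at the preset correlation, adjusted p = 0.0992 with an estimated correlation). The glucose transporter Slc2a1 rose by 0.31 (SE 0.046) and the channel subunit Abcc9 by 0.33 (SE 0.062). Among 17 endothelial markers 4 rose and 10 were higher and 1 lower adjusted over the list alone (adjusted p = 0.294 with an estimated correlation). Among 13 mural markers 2 rose and 4 did adjusted over the list alone (adjusted p = 0.336 with an estimated correlation).

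Within the limits for naming, the genes with the largest increases by genotype included known targets of the glucocorticoid receptor. Plin4 (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803), a lipid-droplet coat protein, rose by 1.16 (SE 0.238, adjusted p = 0.00548), from 29.5 and 30.2 normalised reads in WT females and males to 61.2 and 69.0 in HT. Hif3a rose by 0.79 (SE 0.12) and Il1r1 by 0.52 (SE 0.121). Within the glucocorticoid response list of 25 genes, members moved in both directions. There 8 rose, among them Zbtb16 by 0.52 (SE 0.079) and Fkbp5 by 0.32 (SE 0.068), while 4 fell, among them Dusp1 by 0.99 (SE 0.098) and Per1 by 0.48 (SE 0.057). The counts adjusted over the list alone were also 8 and 4, and the list did not pass as a whole (adjusted p = 0.321, median 0.00, mean 0.11). Dusp1 and Per1 are also members of the immediate early list. Others among the 10 most increased were Colq at 0.67 (SE 0.125), Mlph at 0.64 (SE 0.13), Cilp2 at 0.58 (SE 0.141), Xdh at 0.57 (SE 0.115), Fyb at 0.57 (SE 0.117), Pkp2 at 0.54 (SE 0.104) and the axon guidance receptor Robo3 at 0.53 (SE 0.115).

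Upper-layer excitatory markers rose in 4 of 11, among them Lamp5 by 0.33 (SE 0.069) and Otof by 0.33 (SE 0.081), with 5 higher adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). Of 37 postsynaptic density genes 5 rose, among them Syngap1 by 0.18 (SE 0.04), and Lrrtm4 fell by 0.19 (SE 0.046); 10 were higher and 1 lower adjusted over the list alone (adjusted p = 0.389 with an estimated correlation). Vehicle HT female replicate 3 scored 0.22 on the postsynaptic list, against -0.09 to 0.06 in the other 7 vehicle HT libraries, 0.24 on the upper-layer list, against -0.09 to 0.14, and -1.07 on the olfactory list. Without it 3 postsynaptic genes rose and 1 fell (median 0.07, adjusted p = 0.438 with an estimated correlation), and 3 upper-layer markers rose (median 0.14, adjusted p = 0.322 with an estimated correlation). Of the 37 genes of the PI3K, AKT and mTOR pathway, Inpp5d rose by 0.36 (SE 0.071), and Ddit4 and Irs2 fell by 0.36 (SE 0.09) and 0.35 (SE 0.089). Adjusted over the list alone, 3 of them were higher and 5 lower, and that list did not pass (adjusted p = 0.62). FOXO target genes fell in 5 of 26, which were Kdm6b, Fbxo32, Klf2, Ddit4 and Irs2, and 5 fell adjusted over the list alone (adjusted p = 0.432 with an estimated correlation). Cytosolic ribosomal protein genes had 0 of 80 members called by limma and 0 adjusted over the list alone, and a median of -0.08 (adjusted p = 0.634 with an estimated correlation). Over all genes, limma called 511 for genotype, 319 higher and 192 lower, and edgeR called 496. At the preset correlation 19 of the 58 lists passed, 13 up and 6 down. With an estimated correlation 2 remained, the immediate early and microglia lists. The count fell to 303 without WT female replicate 2, 321 without WT male replicate 1, 325 without WT female replicate 1 and 339 without vehicle HT female replicate 2. It was 866 when fitted on the vehicle groups alone and 1004 with the olfactory score as a covariate.

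By sex, the immediate early list was lower in both. In females 19 of its 30 members fell and 25 fell adjusted over the list alone (median -0.83, adjusted p = 0.0141 with an estimated correlation). In males 23 fell by either adjustment (the count adjusted over the list alone was 23; median -1.14, adjusted p = 0.0001 with an estimated correlation). Among genes within the limits for naming, Egr2 showed the largest fall in males, by 2.37 (SE 0.214). Next came Fosb at -2.31, Fos at -2.15, Atf3 at -2.01 and Ccn1 at -1.94. The most reduced of such genes in females were Atf3 at -2.05 (SE 0.37), Fosb at -1.91, Nr4a3 at -1.60, Fosl2 at -1.57 and Fos at -1.43. Females had 9 of 20 microglia markers higher, 16 adjusted over the list alone (adjusted p = 0.0397 with an estimated correlation), and males 1, or 10 adjusted over the list alone (adjusted p = 0.0681 with an estimated correlation). Extracellular matrix genes passed in males with an estimated correlation (adjusted p = 0.035), where 3 of 27 rose and 9 did adjusted over the list alone. Within the limits for naming, genes most increased were Lct, F2rl2, Robo3, Cited4 and Colq in females, from 0.67 to 0.82. In males they were Hif3a, Mlph, Map3k6, Trpv4 and Acer2, from 0.59 to 1.03. With 1 library left out, Cited4 lost its call in females in 7 of 7 fits, Lct, F2rl2 and Colq in 6 and Robo3 in 5. In males Trpv4 lost its call in 6 of 7 such fits, Mlph in 5, Acer2 in 3 and Map3k6 and Atf3 in 1. The other reduced genes named for each sex, and Hif3a, lost theirs in 0. limma called 261 genes in females (181 higher, 80 lower; edgeR 260) and 83 in males (38 higher, 45 lower; edgeR 74). The test of the difference between the sexes called 0 genes in limma and 0 in edgeR, with 1083 at an unadjusted p under 0.05 in limma. Among the smallest p-values there were those of Dnajc21, Glt8d2, Racgap1 and Nme5, each at adjusted p = 0.755. The female count fell to between 40 and 72 without WT replicates 1 (72), 2 (40) or 3 (64) or HT replicates 2 (68) or 3 (53). The male count fell to 33 without WT replicate 1, 46 without HT replicate 4 and 50 without WT replicate 2, and the difference gained 2 genes without HT male replicate 3 or without WT female replicate 1. In males the count was 232 (138 higher, 94 lower) with the olfactory score as a covariate and 145 (82 higher, 63 lower) without the 4 libraries of lowest olfactory score, so more were higher than lower there. It was 37 (10 higher, 27 lower) when fitted on these groups alone. In females these counts were 292 (191 higher, 101 lower), 151 (89 higher, 62 lower) and 413 (261 higher, 152 lower).

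The fluoxetine comparison asked what the drug changes in HT cortex (n = 8 fluoxetine, n = 8 vehicle). Immediate early genes were higher after fluoxetine. Egr2 (ENSMUSG00000037868, chromosome 10, 67535475 to 67542188), a zinc-finger transcription factor, rose by 0.97 (SE 0.14, adjusted p = 0.00138). It went from 300 (SD 49.9, n = 4) to 549 (SD 52.9, n = 4) normalised reads in females and from 180 (SD 46.1, n = 4) to 369 (SD 34.4, n = 4) in males. Arc rose by 0.87 (SE 0.173), Fosl2 by 0.82 (SE 0.142), Nr4a3 by 0.72 (SE 0.135), and Fos and Nr4a1 by 0.67 (SE 0.138 and 0.108). Of the 30 members 10 rose, 0 fell and 20 did not pass, and 23 rose adjusted over the list alone. The median was 0.38, with adjusted p = 0.00266 with an estimated correlation. The kinase gene Sik1 rose by 0.48 (SE 0.095), the phosphatase Dusp1 by 0.55 (SE 0.091), Csrnp1 by 0.54 (SE 0.08) and the mTOR inhibitor Ddit4 by 0.46 (SE 0.083). Dusp1, Ddit4 and Per1 were the 3 of 25 glucocorticoid response genes that rose, against 9 adjusted over the list alone (adjusted p = 0.0627 with an estimated correlation).

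Fewer genes were lower after fluoxetine. Colq (ENSMUSG00000057606, chromosome 14, 31523082 to 31591343), which anchors acetylcholinesterase, fell by 0.55 (SE 0.116, adjusted p = 0.0454), the potassium channel gene Kcnj2 by 0.35 (SE 0.074) and the clock activator Arntl by 0.30 (SE 0.057). The collagen chains Col4a2 and Col4a1 fell by 0.25 (SE 0.05) and 0.24 (SE 0.046), the 2 called of 27 extracellular matrix genes, with 3 lower adjusted over the list alone (adjusted p = 0.267 with an estimated correlation). Among 21 clock genes Per1 rose by 0.38 (SE 0.052) and Arntl fell, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.10 with 80 of 80 members above 0, and oxidative phosphorylation genes a median of 0.09 with 72 of 75 above 0. limma called 0 members of either list, over all genes or adjusted over the list alone, and both lists had adjusted p = 0.383 with an estimated correlation. Fluoxetine female replicate 3 and male replicate 2 stood apart on both, with ribosomal scores of 0.30 (0.295) and 0.25 (0.249) against -0.107 to 0.0553 in the other 6 fluoxetine libraries. Without these 2 libraries the medians were 0.03 (0.0287) and 0.03 (0.0348), with 64 of 80 and 62 of 75 members above 0. Microglia markers had a median of -0.07, with 0 of 20 called and 1 lower adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). limma called 21 genes, 15 higher and 6 lower, and edgeR called 20. At the preset correlation 20 lists passed, 10 up and 10 down, and with an estimated correlation the immediate early list alone did. With 1 library left out, Egr2, Nr4a1, Fosl2, Dusp1, Csrnp1 and Ddit4 stayed called in 16 of 16 fits, while Arc and Kcnj2 lost their call in 13, Fos, Sik1 and Colq in 12, Col4a2 in 9, Nr4a3 and Col4a1 in 7 and Arntl in 5. The count fell to 11 without fluoxetine female replicate 1, without fluoxetine male replicate 1 or without vehicle HT female replicates 2 or 4, to 12 without fluoxetine female replicate 2 and to 13 without fluoxetine female replicate 3. It was 10 when fitted on these groups alone, 10 higher and 0 lower, so each of the 6 lower genes lost its call there. It was 41 with the olfactory score as a covariate (29 higher, 12 lower) and 19 without the 4 libraries of lowest olfactory score (18 higher, 1 lower). In that last fit Col4a2 stayed called, and Colq, Kcnj2, Arntl and Col4a1 lost their call.

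Within sexes, fluoxetine calls were few. In females 6 genes rose, among them Nr4a1 by 0.78 (SE 0.153), Sox8 by 0.37 (SE 0.067) and Per1 by 0.37 (SE 0.074), and 13 fell, among them Dnajc21 by 0.54 (SE 0.097), Hivep1 by 0.42 (SE 0.066), Palmd, Spred2 and Arid5b. edgeR called 18 in females. In males 7 rose, among them Egr2 by 1.07 (SE 0.198), the insulin signalling adaptor Irs2 by 0.75 (SE 0.116), the glucocorticoid-inducible genes Rasd1 by 0.68 (SE 0.127) and Tsc22d3 by 0.47 (SE 0.091), and Arl4d by 0.51 (SE 0.088), and 1 fell, the clone 4833418N02Rik, by 0.85 (SE 0.156). edgeR called 6 in males. In males 4 lists passed with an estimated correlation. They were glucocorticoid response (adjusted p = 0.00189; 2 of 25 rose, 15 adjusted over the list alone), immediate early genes (adjusted p = 0.00753; 2 of 30, 25 adjusted over the list alone), the unfolded protein response (adjusted p = 0.0217; 1 of 28, 5 adjusted over the list alone) and the circadian clock (adjusted p = 0.025; 1 of 21 rose, with 8 higher and 1 lower adjusted over the list alone). Vehicle HT male replicate 4, in the baseline of this comparison, had an immediate early score of -0.80, against -0.44 to -0.38 in the others of its group. Without it the list's median in males was 0.34 in place of 0.43, with 0 of 30 members called by limma (adjusted p = 0.0284 with an estimated correlation). With each of the 8 libraries left out in turn that adjusted p ran from 0.00587 to 0.0932, and the list did not pass in 1 of the 8 fits. The other lists that passed in males were not refitted in this way with an estimated correlation. Nor are the lists separate, as Per1 belongs to the immediate early, glucocorticoid response and clock lists. In females the immediate early list had 2 of 30 higher, with 17 higher and 2 lower adjusted over the list alone (adjusted p = 0.481 with an estimated correlation), and none of the 25 lists that passed at the preset correlation did so with an estimated one. The test of male minus female called 8 genes in limma and 10 in edgeR. The clock gene Per2 was higher in that difference by 0.90 (SE 0.149, adjusted p = 0.00755), Dnajc21 by 0.76 (SE 0.137), Arid5b by 0.60 (SE 0.113), the glycolytic regulator Pfkfb3 by 0.58 (SE 0.086) and the signalling inhibitor Spred2 by 0.55 (SE 0.084). The unfolded protein response list was also higher in it, by a median of 0.23, with 0 of 28 members called by limma over all genes and 16 adjusted over the list alone (adjusted p = 0.0489 with an estimated correlation). Fluoxetine female replicate 1 had a score of -0.16 on this list, against -0.055 to -0.049 in the others of its group, and without it the median was 0.22 (adjusted p = 0.0783 with an estimated correlation). With each of the 16 libraries left out in turn that adjusted p ran from 0.0208 to 0.204, and the list did not pass in 13 of the 16 fits. Of the genes named here, Arid5b lost its call in the difference in 10 of 16 such fits and Dnajc21 in 3, and Per2, Pfkfb3 and Spred2 in 0. In females Nr4a1, Per1, Palmd and Arid5b lost theirs in 5 of 8 fits, Sox8 in 3, Dnajc21 in 2 and Hivep1 and Spred2 in 0. In males Rasd1 and Tsc22d3 lost theirs in 7 of 8, Egr2 in 6, Arl4d in 5 and Irs2 in 4. When fitted on these groups alone there were 0 calls in males, 6 in females (5 higher, 1 lower) and 4 in the difference. Without the 4 libraries of lowest olfactory score there were 0, 12 and 5, and with the olfactory score as a covariate 12, 76 and 25. Male calls dropped to 0 without fluoxetine replicates 1 or 2 or vehicle replicates 3 or 4, to 3 without fluoxetine replicate 3 and to 4 without vehicle replicates 1 or 2, and rose to 34 without fluoxetine replicate 4. Female calls went to 4 without vehicle replicate 3, 8 without fluoxetine replicates 1 or 3, 10 without vehicle replicates 2 or 4 and 64 without fluoxetine replicate 2, and the difference to 4 without vehicle female replicate 3, 5 without fluoxetine female replicate 3 and 206 without fluoxetine male replicate 4.

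**Figure D2:**
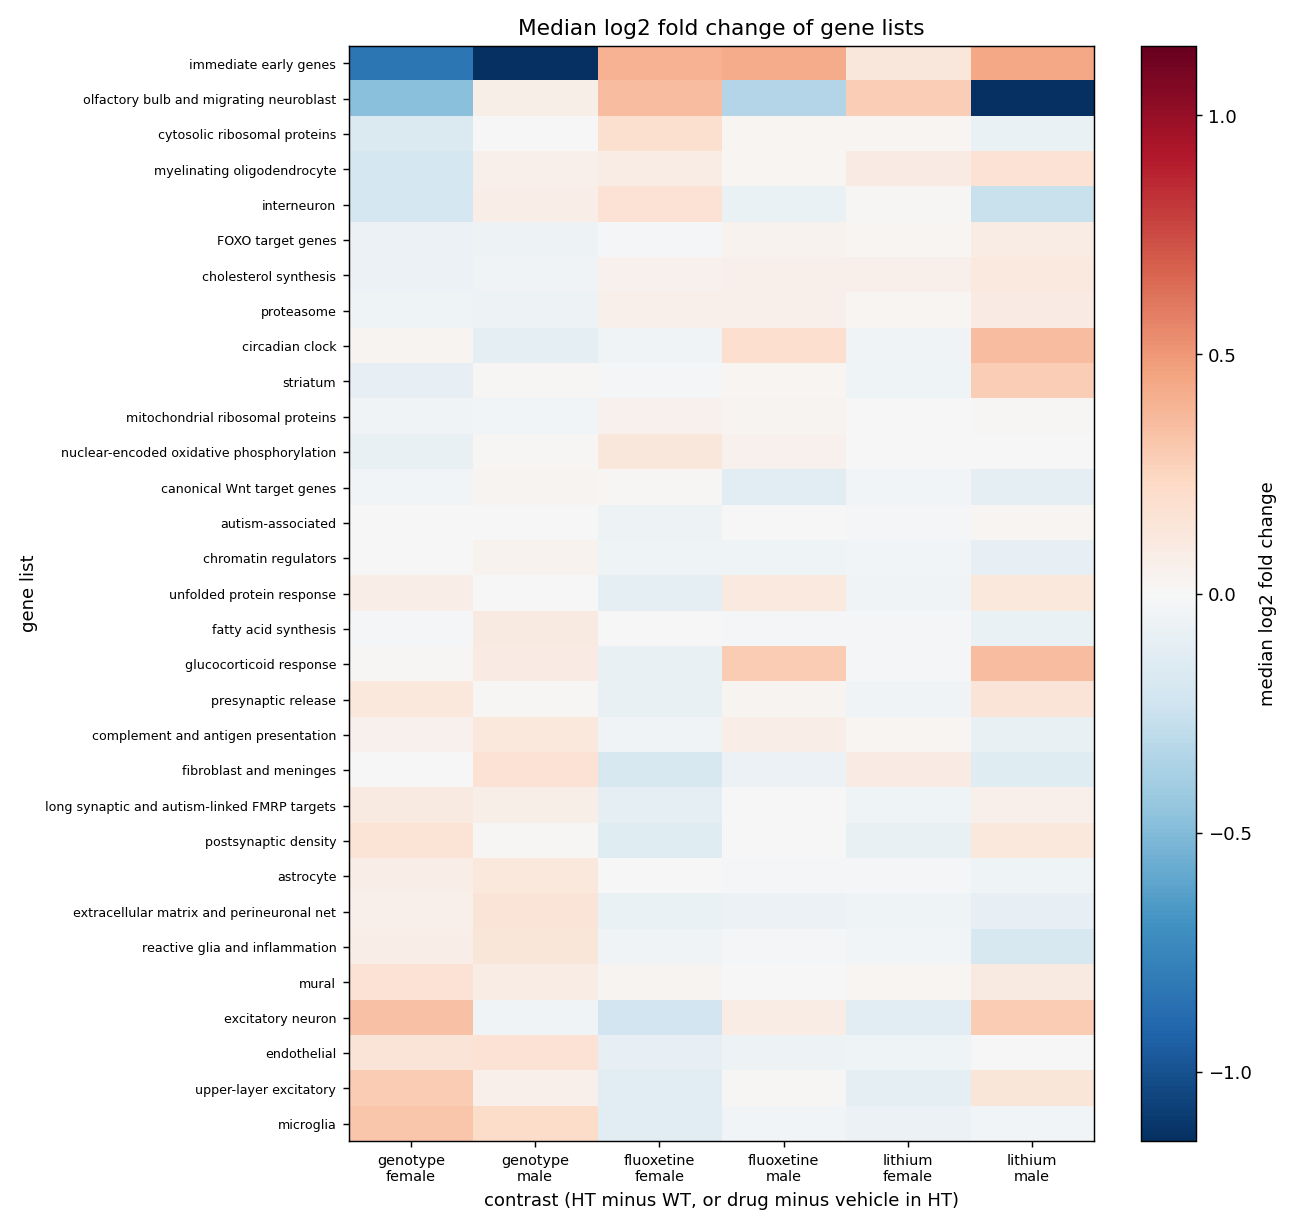
Median log2 fold change of gene lists (vertical axis) for genotype and for each drug within each sex (horizontal axis), on a colour scale. With the sexes averaged, which is not drawn, the immediate early list stood at -0.98 for genotype, 0.38 for fluoxetine and 0.28 for lithium.

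Lithium was compared with vehicle in HT mice in the same way (n = 8 lithium, n = 8 vehicle). Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), a clock repressor that stimuli also induce, rose by 0.34 (SE 0.052, adjusted p = 0.00766). The transcription factors Nr4a3 and Egr2 rose by 0.75 (SE 0.135) and 0.74 (SE 0.14), the clock gene Ciart by 0.48 (SE 0.09) and Irs2 by 0.46 (SE 0.082). Fmo2, a flavin monooxygenase, rose by 0.81 (SE 0.171), Zfp189 by 0.55 (SE 0.091), Csrnp1 by 0.43 (SE 0.08), Arl4d by 0.39 (SE 0.062) and Tsc22d3 by 0.34 (SE 0.065). Of the 30 immediate early genes 3 rose and 27 did not pass, and 20 rose adjusted over the list alone (median 0.28, adjusted p = 0.215 with an estimated correlation). Glucocorticoid response genes rose in 3 of 25, which were Per1, Errfi1 and Tsc22d3, and in 12 adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Clock genes rose in 2 of 21, with 12 higher and 2 lower adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). The T-type calcium channel gene Cacna1g fell by 0.22 (SE 0.04), the only member called of 20 canonical Wnt target genes, with 4 lower adjusted over the list alone (adjusted p = 0.477 with an estimated correlation). The histone deacetylase Hdac4 fell by 0.22 (SE 0.044) among 38 chromatin regulators, with 5 lower adjusted over the list alone (adjusted p = 0.545 with an estimated correlation). Other lower genes were the monoamine transporter gene Slc29a4 at -0.33 (SE 0.071), Sox12 at -0.29 (SE 0.052), and Chsy3, Bahcc1, Tmem108 and Col4a1, from -0.24 to -0.21. Pisd-ps2, annotated as a transcribed pseudogene and so uncertain, was at -0.53 (SE 0.102). None of the 24 inositol metabolism genes was called over all genes or adjusted over the list alone (median 0.02, adjusted p = 0.138). The blood, interferon response, serotonin, dopamine and noradrenaline, lysosome, and PI3K, AKT and mTOR lists passed in none of the 3 main comparisons. limma called 29 genes, 15 higher and 14 lower, and edgeR 27. At the preset correlation 15 lists passed, and with an estimated correlation 0 did. With 1 library left out, Per1, Zfp189, Irs2, Arl4d, Sox12, Bahcc1, Tmem108 and Cacna1g stayed called in 16 of 16 fits. Fmo2 and Slc29a4 lost their call in 12, Chsy3 in 11, Col4a1 in 10, Hdac4 in 6, Egr2 in 4, Pisd-ps2 in 3, Nr4a3, Csrnp1 and Ciart in 2 and Tsc22d3 in 1. Egr2 lost it without lithium female replicate 2 (adjusted p = 0.0551), lithium male replicates 1 (0.0594) and 2 (0.0504) or vehicle HT female replicate 2 (0.0596). The count was 11 without lithium female replicate 2, 12 without lithium male replicate 1, 15 without vehicle HT female replicate 2, 17 without lithium female replicate 4 or vehicle HT male replicate 4, 60 without lithium male replicate 3 and 132 without vehicle HT female replicate 3. It was 625 (280 higher, 345 lower) when fitted on these groups alone, 78 (38 higher, 40 lower) with the olfactory score as a covariate and 120 (46 higher, 74 lower) without the 4 libraries of lowest olfactory score.

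Lithium was also tested within each sex. In males (n = 4 lithium, n = 4 vehicle) limma called 2568 genes, 1206 higher and 1362 lower, and edgeR 2488. In females it called 0, with 505 at an unadjusted p under 0.05, and edgeR called 0 with 498. The test of male minus female itself called 319 genes, 147 higher and 172 lower, and edgeR 268. In males Fmo2 rose by 1.47 (SE 0.242), Egr2 by 1.18 (SE 0.198), Nr4a3 by 1.15 (SE 0.191), the melanocortin receptor gene Mc4r by 1.15 (SE 0.208) and Plin4 by 1.21 (SE 0.312). Of 25 glucocorticoid response genes 15 rose in males, among them Tsc22d3 by 0.68 (SE 0.091) and Errfi1 by 0.52 (SE 0.076), and 18 adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation). Clock genes rose in 14 of 21 and fell in 1, with 15 and 2 adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation), led by Per2 at 0.81 (SE 0.105). Immediate early genes rose in 18 of 30 and in 20 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). In the difference between sexes Mc4r was higher in males by 1.59 (SE 0.295), Fmo2 by 1.33 (SE 0.342), Fosb by 1.15 (SE 0.278), Per2 by 1.12 (SE 0.149) and Irs2 by 1.03 (SE 0.164). Chrna10 was lower there, at -2.23 (SE 0.547), with Rhcg at -2.17, the water channel gene Aqp1 at -1.99, Ltbp2 at -1.74 and Capn6 at -1.56. With 1 library left out, Mc4r, Per2 and Irs2 stayed called in this difference in 16 of 16 fits. Ltbp2 lost its call in 13, Fmo2 in 11, Fosb and Chrna10 in 10, Aqp1 and Rhcg in 7 and Capn6 in 1. With the olfactory score as a covariate Per2 stayed called in the difference, and the other 9 of these 10 genes lost their call. Without the 4 libraries of lowest olfactory score Per2 and Irs2 stayed called, and the other 8 lost theirs. Within the limits for naming, the smallest p-values in females belonged to Tmem108 at -0.30 (SE 0.059), Smad3 at -0.32 (SE 0.068), Etv6, Camk1g and Kcnj2, with adjusted p from 0.322 to 0.611.

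Olfactory transcripts fell in the same lithium-treated males. The olfactory marker gene Omp (ENSMUSG00000074006, chromosome 7, 98143359 to 98145502) fell by 2.46 (SE 0.585, adjusted p = 0.00865), from 620 (SD 235, n = 4) to 121 (SD 75.5, n = 4) normalised reads. Stoml3 and S100a5, both of olfactory sensory neurons, stood at -2.32 (SE 0.613) and -2.28 (SE 0.575), and Clca3a1 at -2.63 (SE 0.614). Fam205a3, at -4.54 (SE 1.53), belongs to a family of near-identical genes and is uncertain. With 1 library left out, Fam205a3 lost its call in 6 of 8 fits and Stoml3 in 2. Of 15 olfactory bulb and migrating neuroblast markers 11 fell, among them Doc2g by 1.83 (SE 0.43) and Th by 1.82 (SE 0.433), and 14 fell adjusted over the list alone (median -1.15, adjusted p = 0.461 with an estimated correlation). The members are strongly tied, with an estimated correlation of 0.912. The list's score was lower in lithium than in vehicle males by a difference of -1.17, at exact 2-sided permutation p = 0.0286, the smallest that 4 against 4 allows, and adjusted p = 0.171 over the 6 comparisons. Markers of interneurons, of which the olfactory bulb holds many, fell in 10 of 20 and rose in 1, with 12 lower and 3 higher adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Striatal markers rose in 6 of 16, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.488 with an estimated correlation). Their score was 0.929 in lithium male replicate 3, the highest of all libraries. The striatum and blood scores gave no call between lithium and vehicle males (differences 0.20 and 0.12, exact permutation p = 0.771 and p = 0.714). With the olfactory score as a covariate the male count was 300 (183 higher, 117 lower), of which 146 were among the 2568. The balance thus turned from that of the 1206 higher and 1362 lower genes. Fmo2, Egr2 and Nr4a3 stayed called in males there, and Mc4r, Plin4, Omp, Stoml3, S100a5, Clca3a1 and Fam205a3 lost their call. The difference between sexes had 5 genes (3 higher, 2 lower), of which 3 were among the 319. Without the 4 libraries of lowest olfactory score the male count was 1547 (656 higher, 891 lower) and the difference 17 (13 higher, 4 lower), of which 13 were among the 319. Plin4 and Fam205a3 lost their call in males there. The male count was 1393 without vehicle replicate 3, 1586 without vehicle replicate 4 and 1668 without lithium replicate 4, and the female count 1 without vehicle replicate 1. The difference between sexes ranged from 28 to 496 with 1 library left out, and 11 of the 16 libraries moved it by more than 1.5 times. It was 28 without lithium female replicate 3, 77 without replicate 4 and 130 without replicate 1; 50 without vehicle female replicate 3 and 146 without replicate 4; 65, 94 and 206 without vehicle male replicates 3, 4 and 1; and 110, 123 and 496 without lithium male replicates 4, 1 and 2.

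**Figure D3:**
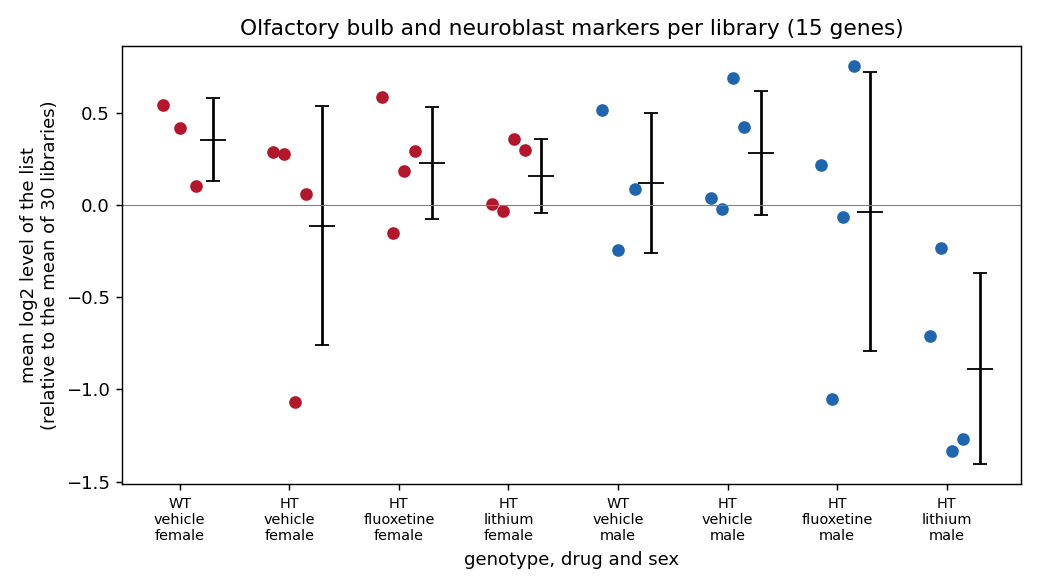
Score of the olfactory bulb and migrating neuroblast list (mean centred log2 level) in each library, by group, with the group mean and the standard deviation of its libraries. Lithium-treated HT males lay between -1.34 and -0.23, and vehicle HT males between -0.02 and 0.69.

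Genotype and drug effects were then set against each other, to ask whether the drugs moved genes back. Every gene called for fluoxetine was called for genotype in the opposite direction. All 15 genes that rose with fluoxetine, among them Egr2, Arc, Fos, Nr4a1, Per1 and Ddit4, had fallen in vehicle HT mice, where independent lists would share 0.172. All 6 that fell, among them Colq, Kcnj2, Arntl, Col4a1 and Col4a2, had risen, against 0.114. For lithium 9 of the 15 higher genes had fallen by genotype (0.172 for independent lists), among them Egr2, Nr4a3, Per1, Ciart and Irs2, and 4 of the 14 lower genes had risen (0.266), among them Col4a1 and Tmem108. The drugs shared 6 higher genes, Arl4d, Csrnp1, Egr2, Nr4a3, Per1 and Sox8 (0.0134 for independent lists), and 1 lower gene, Col4a1 (0.00501). Vehicle HT libraries enter the genotype and drug effects with opposite signs and the 2 drug effects with the same sign, so none of these overlaps is by itself evidence of a shared or reversed effect. Lists of the same sizes, taken by p-value from 100 regroupings of residuals that carry no effect, shared a mean of 4.47 (higher with fluoxetine) and 2.20 (lower) with genotype. For lithium they shared 4.15 and 4.07, and for the 2 drugs 1.33 and 0.40. The 4 lower lithium genes shared with genotype were thus no more than lists without an effect gave, and 32 of 100 regroupings shared at least 1 lower gene between the drugs. At least as many as observed were shared in 0 and 1 of 100 for fluoxetine with genotype, 3 for higher genes of lithium with genotype, and 1 for higher genes of the 2 drugs. With separate vehicle HT mice for each effect, over 36 partings of those 8 mice, fewer genes were called. Fluoxetine then had a mean of 6.72 higher and 0.694 lower genes, of which 5.33 and 0.472 were called for genotype in the opposite direction. Lithium had 3.50 and 1.58, of which 1.81 and 0.0833 were so called. The drugs shared a mean of 0.361 higher genes and 0 lower. With separate vehicle HT mice for each effect, the immediate early median was -0.98 for genotype (from -1.10 to -0.84 over the 36 partings) and 0.40 for fluoxetine (from 0.32 to 0.51). For lithium it was 0.28 (from 0.16 to 0.40), and the signs were opposite in 36 of 36 partings for each drug. A state at collection shared by all 8 vehicle HT mice would give opposite signs as well. Across all 16780 genes, which are not independent replicates, the genotype effect correlated with that of fluoxetine at r = -0.518 and with that of lithium at r = -0.350. The fluoxetine and lithium effects correlated at r = 0.442. Regrouped residuals, which carry no effect but share the vehicle HT libraries, gave a mean r of -0.476 (SD 0.125), -0.460 (SD 0.128) and 0.519 (SD 0.144). The covariances were -0.0136, -0.0113 and 0.0108, against simulated means of -0.00984 (SD 0.00372), -0.00968 (SD 0.00395) and 0.00994 (SD 0.00371). These genome-wide values were therefore not beyond what the shared libraries give.

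Fluoxetine HT and lithium HT differed in 2 genes (n = 8 each), by limma and by edgeR. Mx2, an interferon-induced GTPase named here after its values were seen, was higher with fluoxetine by 0.71 (SE 0.121, adjusted p = 0.0352), and the pseudogene Pisd-ps2 by 0.58 (SE 0.102, adjusted p = 0.0352). No gene was lower by limma, where 2896 genes of either sign had an unadjusted p under 0.05. Both calls were lost when any 1 of 10 of the 16 libraries was left out, which were fluoxetine female replicates 1, 3 and 4, fluoxetine male replicates 1 and 4, lithium female replicates 1, 2 and 4 and lithium male replicates 1 and 3, each with 0 calls. Pisd-ps2 lost its call in 13 of the 16 fits, the further 3 being those without fluoxetine male replicate 3, lithium female replicate 3 and lithium male replicate 2. The count was 0 with the replicate block and with the stricter filter, which left Mx2 untested, and 1 when fitted on these groups alone. Both were lost too with the olfactory score as a covariate and without the 4 libraries of lowest olfactory score, where Pisd-ps2 had adjusted p = 0.0559 and 0.0527. In each of these fits 3 other genes were called. The count was 1 without lithium female replicate 3, 203 without fluoxetine male replicate 2 and 456 without fluoxetine female replicate 2.

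Drug-treated HT mice were also compared with vehicle WT mice, to ask what remained different under treatment; genotype and drug both differ here. Immediate early genes stayed below WT levels under both drugs. With fluoxetine 18 of 30 were lower and 20 adjusted over the list alone (median -0.52, adjusted p = 0.0071 with an estimated correlation). With lithium 21 were lower and 24 adjusted over the list alone (median -0.73, adjusted p = 0.0247 with an estimated correlation). Microglia markers were higher in 4 of 20 with fluoxetine, 13 adjusted over the list alone (adjusted p = 0.0695 with an estimated correlation), and in 11 with lithium, with 16 higher and 1 lower adjusted over the list alone (adjusted p = 0.124 with an estimated correlation). Glucocorticoid response genes rose in 8 and fell in 1 of 25 with fluoxetine, with 12 and 2 adjusted over the list alone (adjusted p = 0.0695 with an estimated correlation). With lithium 11 rose and 1 fell, with 13 and 2 adjusted over the list alone (adjusted p = 0.124 with an estimated correlation). limma called 81 genes for fluoxetine HT against WT (54 higher, 27 lower; edgeR 82) and 778 for lithium HT against WT (463 higher, 315 lower; edgeR 759). The fluoxetine count was 50 without WT female replicate 2, 142 without fluoxetine male replicate 4, 34 (12 higher, 22 lower) when fitted on these groups alone and 157 with the olfactory score as a covariate. The lithium count was 302, 328, 376 and 451 without WT male replicate 1, WT female replicates 1 and 2 and WT male replicate 3, and 380, 419 and 437 without lithium female replicates 2 and 1 and lithium male replicate 4, and 257 with the olfactory score as a covariate. It was 2217 when fitted on these groups alone and 528 without the 4 libraries of lowest olfactory score.

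Between the sexes, limma called 12 genes in vehicle mice, all on the X or Y chromosome. Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) and 3 other Y-linked list members were higher in males, with Uba1y and Gm29650, named after their values were seen. Xist, Eif2s3x, Kdm6a, Kdm5c, Ddx3x and 5530601H04Rik were lower in males, 6 of the 7 X inactivation and escape genes. Eif2s3x, which escapes X inactivation, was at -0.59 (SE 0.041). All 4 members of the Y chromosome list rose and 6 of 7 of the X list fell, the same counts adjusted over the list alone, and both lists passed with an estimated correlation (adjusted p = 8.94e-13 and 8.97e-08). Interferon response genes were lower in males by a median of -0.28, with 29 of 30 below 0 (adjusted p = 0.0282 with an estimated correlation). limma called 0 of them over all genes and 16 adjusted over the list alone. Late activity-response genes were lower by a median of -0.07, with 20 of 23 below 0, 0 called by limma over all genes and 4 adjusted over the list alone (adjusted p = 0.0282 with an estimated correlation). Over all genes 499 had an unadjusted p under 0.05 in limma, and edgeR called 12.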

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

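The test at equal olfactory score, the tests of time of day and of handling, and the 2 tests on the genes that differ most by genotype were chosen after the result was seen. The other tests were written before they were run, but the counts with the olfactory score as a covariate had been seen by then.

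The 6 groups of 4 libraries were tested for 1 library apart from the rest on 10 measures each. Of these 60 tests 3 marked one, where chance alone marks about 1 in 20. Vehicle HT male replicate 4 had an immediate early gene score of -0.80, against -0.44 to -0.38 in the others of its group. Vehicle HT female replicate 3 had an olfactory score of -1.07, against 0.06 to 0.29. Fluoxetine HT female replicate 1 had an unfolded protein response score of -0.16, against -0.055 to -0.049.

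Genes called in the male minus female difference of a drug effect were the other results marked for a closer look. For fluoxetine 8 genes were called in that difference, with Per2 at 0.90, Dnajc21 at 0.76, Arid5b at 0.60, Pfkfb3 at 0.58 and Spred2 at 0.55, and the unfolded protein response list had a median of 0.23 (0.226). For lithium 319 were called (5 with the olfactory score as a covariate), with Mc4r at 1.59, Fmo2 at 1.33, Fosb at 1.15, Per2 at 1.12 and Irs2 at 1.03, and with Chrna10 at -2.23, Rhcg at -2.17, Aqp1 at -1.99, Ltbp2 at -1.74 and Capn6 at -1.56.

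The many genes called in lithium-treated males were weighed against a lower share of olfactory bulb or neuroblast tissue in those dissections. Slopes on the olfactory score, taken from the 6 groups outside this comparison, predicted the observed log2 fold changes of 2557 called genes outside the olfactory list at r = 0.858, with 92.6% of the same sign. Over all genes outside that list, called or not, r was 0.630. These values fit the tissue explanation, although genes are not independent replicates and any structure of the samples along the same axis would do the same. With the olfactory score as a covariate 300 genes were called, and 2 of the 35 splits of these 8 males called as many, the highest other split 1051. Lithium and vehicle males did not overlap in olfactory score, so no mice were compared at equal score and the covariate is tied to treatment. An effect of lithium in males at equal olfactory score therefore cannot be told apart from other structure in these samples.

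The lower immediate early genes in vehicle HT mice were weighed against tissue share, time of day and handling. Another share of olfactory bulb tissue was argued against, since the list's median was -0.99 with the olfactory score as a covariate (adjusted p = 0.0017 with an estimated correlation). Another time of day at collection stays open, with 5 of 20 clock genes outside the list called and a median absolute log2 fold change of 0.097 against 0.976. Among the called genes Arntl was higher by 0.42, and Nfil3 (-0.57), Ciart (-0.46), Dbp (-0.34) and Nr1d2 (-0.25) were lower. A shift in time would move clock genes with the sign of their phase, so opposite directions do not argue against it. Another handling or arousal state of the vehicle WT mice also stays open, because the list's members varied together within groups (correlation 0.361), although the within-group SD of 0.142 was far below the mean difference of -0.94 (-0.941). The result may thus reflect genotype or the state of the mice at collection.

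Drug effects opposite to the genotype effect were weighed against the vehicle HT libraries shared by both. With separate vehicle HT mice the mean covariance across all genes was -0.00537 for fluoxetine and -0.00311 for lithium, reached by 12 and 23 of 100 regroupings of residuals. Shared vehicle HT libraries thus fit the genome-wide pattern for both drugs. For the genes that differ most by genotype, chosen in separate mice, the mean r was -0.732 for fluoxetine (0 of 100 regroupings as low) and -0.448 for lithium (4 of 100). Shared libraries as such cannot give that r, because genotype and drug effects used different vehicle HT mice there. However, each regrouping chose its own genes from residuals without a genotype effect. Its spread need not hold for chosen genes that vary together, as the immediate early genes do, so chance was not excluded. Without drug-treated WT mice, a reversal could not be separated from a drug effect unrelated to genotype. Nor could either be separated from a state of the vehicle HT mice at collection, which both sets of those mice would share.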

How the results depend on the processing

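Groups of 3 or 4 libraries limit what these counts can carry, and counts of called genes moved more than directions did. A further TMM rescaling, no filter, the stricter filter and an added value of 5 left every direction unchanged, and 127 to 130 named genes and 60 to 63 list results kept their side of the threshold. The stricter filter left 0 genes for fluoxetine against lithium, where Mx2 was not tested because its mean lies below 50, and the cause for Pisd-ps2 was not tested. TMM rescaling gave the male minus female difference of fluoxetine 8 higher and 1 lower in place of 8 and 0. edgeR kept 122 named genes and moved no count of genes by over 1.5 times. Without trend and robust estimation 19 named genes lost their call, and fluoxetine in males had 4 genes, the male minus female difference of lithium 182 and fluoxetine against lithium 1; the cause was not tested.

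Replicate numbers did not pair libraries, as the mean correlation of residuals over 99 pairs of the same number was -0.00334. The replicate block left 0 genes for fluoxetine against lithium and changed no other count by over 1.5 times; the cause was not tested.

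Fits on only the groups compared use fewer samples to estimate the spread and leave out the spread of the other groups. They called 866 genes for genotype, 10 for fluoxetine and 625 for lithium, and 413 for genotype in females, 37 for genotype in males, 6 for fluoxetine in females and 0 for fluoxetine in males. The male minus female difference was 4 for fluoxetine and 1436 for lithium. Fluoxetine against lithium gave 1, fluoxetine HT against WT 34 and lithium HT against WT 2217. In these fits 102 named genes kept their side of the threshold and 29 lost their call. Counts moved both ways from the main fits, and the cause was not tested.

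With the olfactory score as a covariate the counts were 1004 for genotype, 41 for fluoxetine, 78 for lithium, 76 for fluoxetine in females, 1 for lithium in females, 232 for genotype in males and 300 for lithium in males. The male minus female differences were 25 for fluoxetine and 5 for lithium, and the drug-treated HT groups against WT 157 and 257. Pten turned from -0.02 to 0.00676 for genotype, and 2 lists reversed for lithium, excitatory neuron (adjusted p = 0.329) and presynaptic release (adjusted p = 0.0316). Without the 4 libraries of low olfactory score the counts were 120 for lithium, 151 for genotype in females, 145 for genotype in males, 12 for fluoxetine in females, 0 for fluoxetine in males and 1547 for lithium in males, with differences between the sexes of 5 for fluoxetine and 17 for lithium. Of the named genes 23 lost their call with the covariate and 31 without the 4 libraries, and 6 list results were lost under each. Without the library of high striatum score 9 named genes and 5 list results were lost, lithium had 60 and fluoxetine against lithium 0. The cause of these changes was not tested.

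With an estimated correlation 2, 1 and 0 lists passed for genotype, fluoxetine and lithium, in place of 19, 20 and 15, because that setting widens the null for lists whose members vary together. Camera on ranks kept 58 list results and lost 5. On genes called for genotype the correlations of effects were -0.872 for genotype with fluoxetine, -0.628 for genotype with lithium and 0.765 for fluoxetine with lithium, on genes chosen for a large genotype effect. Groups without a change, sharing the vehicle HT libraries, gave -0.421 (SD 0.212), -0.431 (SD 0.209) and 0.474 (SD 0.201), so the value for lithium lay within 1 SD of that.

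With 1 library left out, counts ran from 303 to 551 for genotype, 11 to 25 for fluoxetine, 11 to 132 for lithium, 40 to 226 for genotype in females, 33 to 71 in males, 4 to 64 for fluoxetine in females, 0 to 34 in males, 0 to 1 for lithium in females and 1393 to 2334 in males. Differences between sexes ran from 0 to 2 for genotype, 4 to 206 for fluoxetine and 28 to 496 for lithium. Fluoxetine against lithium ran from 0 to 456, fluoxetine HT against WT from 50 to 142, lithium HT against WT from 302 to 950 and sex from 10 to 14. Lists called ran from 16 to 25 for genotype, 18 to 22 for fluoxetine and 12 to 20 for lithium. Correlations of effects across all 16780 genes ran from -0.569 to -0.447 for genotype with fluoxetine and -0.418 to -0.269 for genotype with lithium. For fluoxetine with lithium they ran from 0.318 to 0.552. Pten ran from -0.0475 to 0.0131 for genotype, -0.0225 to 0.0541 for fluoxetine and 0.03 to 0.10 for lithium. The cause of these changes was not tested.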

Other observations

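No test in this part was chosen after the result was seen, other than the splits with the olfactory score as a covariate. The libraries of each comparison were split in other ways, and the genes called were counted, to ask whether groups drawn at random could give as many. Counting the real split, 1 of 100 splits was as large for genotype (real 511, highest other 70), lithium HT against vehicle WT (real 778, highest other 22) and sex (real 12, highest other 1). It was 1 of 35 for genotype in females (real 261, highest other 5) and in males (real 83, highest other 20). The same held for fluoxetine in females (real 19, highest other 1) and lithium in males (real 2568, highest other 1). Chance was thus argued against, not excluded. Shares were not adjusted over the comparisons, and 1 of 35 (0.0286) is the smallest share that 35 splits allow. With the olfactory score as a covariate 2 of 35 splits were as large for lithium in males. For fluoxetine in females the fit on its own groups called 6 genes, of which 3 were among the 19.

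Some splits called several times the real count, which points to a structure of the samples other than the groups. That held for fluoxetine (3 of 100; real 21, highest other 2006), lithium (4 of 100; real 29, highest other 865) and the male minus female difference of fluoxetine (4 of 100; real 8, highest other 1872). It held also for that of lithium (2 of 100; real 319, highest other 1035) and for fluoxetine HT against vehicle WT (2 of 100; real 81, highest other 1015). In each of these 5 the share of splits as large lay under 0.05. Since some splits called far more genes than the real one, these shares did not argue against chance there. Nor did those for fluoxetine in males (2 of 35, real 8, highest other 1332) or fluoxetine against lithium (7 of 100, real 2, highest other 1053). With 0 genes called by limma and by edgeR, lithium in females (35 of 35; highest other 0; 505 at an unadjusted p under 0.05 in limma) and the male minus female difference of genotype (100 of 100; highest other 24; 1083 at an unadjusted p under 0.05) gave nothing to exclude.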
